A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

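Total RNA of a strain labelled pob3 and of a wild-type strain was hybridised to 2 spotted arrays of S. pombe open reading frames, with the dyes swapped between them. The deposited scanner values are intensities, given per the file headers as the median brightness of each spot and of its local background in each channel, with 1 file for each of the 2 duplicate spots of an array and 5760 spots in 32 blocks per file. Quantification software is not given in the sources used here. The channels are named mutant and wild type per the file headers, and the dyes come from the labels. Per the series' design text, the authors normalised with intensity-dependent Lowess in GeneSpring and listed genes at a threshold of 2.0. The deposited table of processed values holds log2 ratios whose scale and direction were found by setting them against the scanner values. For replicate 2 they had an r of 0.977 with the log2 ratios computed here, in the direction pob3 over wild type. For replicate 1 the column holds 768 values with 36 distinct levels, 0 of them on gene spots, so its scale, centring and direction stay unknown and it was not used. The column medians were -0.12 and -0.04.

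Background was corrected with normexp (offset 50), and each spot file was normalised by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The sign of each ratio was turned to pob3 over wild type. A spot was kept with a quality flag of 0 and a signal above background in at least 1 channel. Above background meant over 2 background SDs in Cy3, or over 1.5 times the background in Cy5. The files give a single background SD without naming its channel, and it was taken from its values to be that of Cy3. No SD was thus at hand for Cy5, so that its limit was set once the files had been seen. Median gene signals per file were 1977.5 to 4442 in Cy3 and 5083 to 6300 in Cy5, with median backgrounds of 8.5 to 16 and 545 to 599. Spots of a gene were averaged to 1 value per array, so that an array counts once. The test was limma's lmFit and eBayes of the mean against 0, with Benjamini-Hochberg adjustment over 4766 genes at 0.05. With 1 residual degree of freedom per gene the test rests on the spread pooled over genes (prior degrees of freedom 9.71, prior SD 0.37). The ratio is only a bound for genes not above background or saturated in 1 channel on both arrays. Such genes kept their ratios in the tests and list means. Saturation on both arrays marked 53 genes in 1 channel and 82 in both. None of the 25 genes past the threshold was among these, and hta2 and htb1 were saturated in the pob3 channel.

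Names on the array are those of its design. Of 5048 gene-like names, 4614 matched 1 locus of a reference table (assembly ASM294v3), which served only for current names and for which genes neighbour each other. A further 61 matched several loci and 193 matched none. Left out were control spots, 154 names marked missing, 25 reporter, intergenic or intronic probes and 1 name turned into a date. The reporter, intergenic, intronic and date-named probes were left out after the data were seen, and the count of genes past the threshold was 25 with or without them. Also after the data were seen, list members were restricted to genes whose current symbol matches.

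The 25 fixed gene lists and 3 positional lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, for lists of at least 5 measured members. With an estimated correlation camera is limited to the 1 residual degree of freedom of 2 arrays, so it can pass hardly any list. The same limit holds for fry as a test of change in 1 direction. Positional lists hold the 25 genes nearest each end of chromosomes I and II, 10 genes on each side of each centromere and 5 on each side of pob3. Fixed lists not described singly in the results are mating type and pheromone response, meiosis and sporulation, ribosome biogenesis, glycolysis, phosphate and thiamine regulated, hexose transporter and sugar utilisation, auxotrophic and marker loci, MBF-regulated G1/S, DNA damage response, cell surface, adhesion and flocculation, and chromatin remodeller genes. Their means lay between -0.04 and 0.09 and their adjusted p-values between 0.486 and 0.978. Named genes were pob3, spt16, the 12 highest and 12 lowest past the threshold with the same sign on both arrays, filled up where fewer passed from genes over 2-fold on both, up to 4 members with the smallest p of each described list, and swi6, clr4, ago1, dcr1, rdp1 and epe1. Only 11 lower genes met the rule. The remaining genes past the threshold, ctt1, fbp1, ctr4 and the genes of the closing part were chosen after their values were seen.

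The test was checked on 20 simulated data sets of 4766 genes with 200 changed. Median recovery was 100% of 4-fold and 56% of 2-fold changes (8% to 71%). The share of false calls had a median of 11.9% and reached 19.4%, above the nominal 5%, and the cause was not tested. In the 9 of 20 sets whose prior degrees of freedom were under 20, as in the real data, the median share was 2.4%. The simulation held no effects of print position or block and no gene-specific dye bias, so 2.4% is not the share in the real data. A stricter limit on false calls, set first for a single simulated set, was not met. It was replaced after that result by a median under 20% over the 20 sets, so this check was loosened. A list shifted by 0.5 was found in 20 of 20 sets, and 1 of 400 unshifted lists was called. The simulated genes varied independently of each other. Real lists can be correlated, as for ribosomal protein genes (estimated correlation 0.214), so this does not check the list test for such lists.

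Apart from the choices said here to have been made once the files or data were seen, the analysis choices, lists and most alternatives were fixed before the data were examined. Alternatives covered the background correction, normalisation, spot filter, use of single spot files, the test and the thresholds. The subtraction of print position medians, alone or with print-tip loess, the use of the submitters' values for replicate 2 and the lists without misassigned members were added after the data were seen. The original settings were kept although most alternatives called more genes.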

Results

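Transcript levels of the fission yeast Schizosaccharomyces pombe were compared between a strain labelled pob3 and a wild-type strain on 2 spotted arrays of open reading frames. Pob3 is a subunit of FACT, a histone chaperone that it forms with Spt16. The series concerns FACT, silent chromatin at centromeres and RNA interference, and the arrays address which transcripts differ in the pob3 strain. Each array carried both RNAs, with pob3 RNA in Cy5 on replicate 1 and in Cy3 on replicate 2, so the dyes were swapped. Each gene was spotted in duplicate. Between 96.6% and 98.2% of gene spots lay above background in Cy3 and between 98.3% and 98.8% in Cy5, against 1.33% to 2.66% and 5.50% to 7.02% of empty and buffer spots. A total of 4766 genes were measured on both arrays. Values are log2 ratios of pob3 over wild type, given as mean ± SD over the arrays (n = 2), and the number of arrays limits their precision. The labels do not say whether the arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

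The pob3 transcript itself had a log2 ratio of -1.26 ± 0.20, with -1.40 on replicate 1 and -1.12 on replicate 2, and an adjusted p of 0.0612 (limma, Benjamini-Hochberg) that missed the threshold of 0.05. Its probe stayed above background in the pob3 channel on both arrays. The labels do not describe the allele, and a probe outside an altered part of the gene would check nothing. The transcript of spt16, the other FACT subunit, had a log2 ratio of -0.01 ± 0.12 (adjusted p = 0.993).

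The strongest differences were higher levels in pob3 of a subtelomeric helicase gene, of iron uptake genes and of a small heat shock gene. The transcript of tlh1, which encodes a RecQ-family helicase and lies next to a chromosome end, rose by 4.11 ± 0.68 (17.2-fold, adjusted p = 0.000134). Near-identical copies of this gene lie at other chromosome ends, so its probe can report several of them. Next came str3, of the siderophore transporter family (2.92 ± 0.28, 7.55-fold, adjusted p = 0.000634), and frp1, a ferric reductase (2.78 ± 0.66, 6.89-fold, adjusted p = 0.00201). The small heat shock gene hsp16 rose by 2.16 ± 0.76 (4.47-fold, adjusted p = 0.0118). The strongest decrease was that of vht1, a biotin transporter gene, at -1.98 ± 0.17 (adjusted p = 0.0112).

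In all, 25 of the 4766 genes passed an adjusted p of 0.05, 21 of them higher and 4 lower in pob3, and each lay over 2-fold in the same direction on both arrays. The other genes among the 12 highest were SPAC750.07c (1.87 ± 0.03), SPAC29A4.06c (1.86 ± 0.05), the proteinase inhibitor gene pbi2 (1.85 ± 0.12), urg1 (1.84 ± 0.77), the iron permease gene fip1 (1.70 ± 0.12), the lysine biosynthesis gene lys7 (1.68 ± 0.48), the multicopper oxidase gene fio1 (1.66 ± 0.04) and urg2 (1.60 ± 0.23). Their adjusted p-values lay between 0.0112 and 0.0268. Without the filter on dim and marked spots SPAC29A4.06c had a log2 ratio of 0.74 (adjusted p = 0.498). The 9 other genes that rose were cox1 (1.59), fta6 (1.55), klp8 (1.52), pim1 (1.47), SPAC212.08c (1.47), srp14 (1.47), SPAC19G12.09 (1.46), bdc1 (1.44) and shf1 (1.40). Besides vht1, SPCC965.14c (-1.71 ± 0.35), SPAC694.03 (-1.45 ± 0.44) and the diphthamide synthesis gene dph4 (-1.39 ± 0.20) fell, with adjusted p-values between 0.0200 and 0.0461. At an unadjusted p of 0.05 there were 353 genes, against 238.3 expected by chance.

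By the submitters' own threshold of 2-fold, applied here on both arrays and without a test, 36 genes were higher and 11 lower, where 3.2 and 0.360 would be expected if the arrays were unrelated. Another 13 genes were over 2-fold lower on replicate 1 and higher on replicate 2, brighter in Cy3 on both, against 1.72 expected, and 0 went the other way, against 0.671. The lower genes that did not pass the test were sou1, a sorbitol utilisation gene (-1.50 ± 0.66, adjusted p = 0.0518), pob3 itself, the ribosomal protein gene rps1002 (-1.23 ± 0.15), the translation initiation factor gene tif1102 (-1.13 ± 0.03), the dUTPase gene dut1 (-1.13 ± 0.09), sdh7 (-1.10 ± 0.05) and the vitamin B6 synthesis gene snz1 (-1.05 ± 0.07). Across all genes the log2 ratios of the arrays correlated weakly (Pearson r 0.155, Spearman rho 0.105), and the Pearson r turned to -0.0729 when each spot file was centred on its median instead of loess. Genes are not independent replicates. Duplicate spots within an array correlated at 0.756 and 0.847. The count of 25 was 0 with median centring, where 174 genes had an unadjusted p under 0.05 in limma. It was 62 when medians of print positions were subtracted, a setting added after the data were seen.

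**Figure D1:**
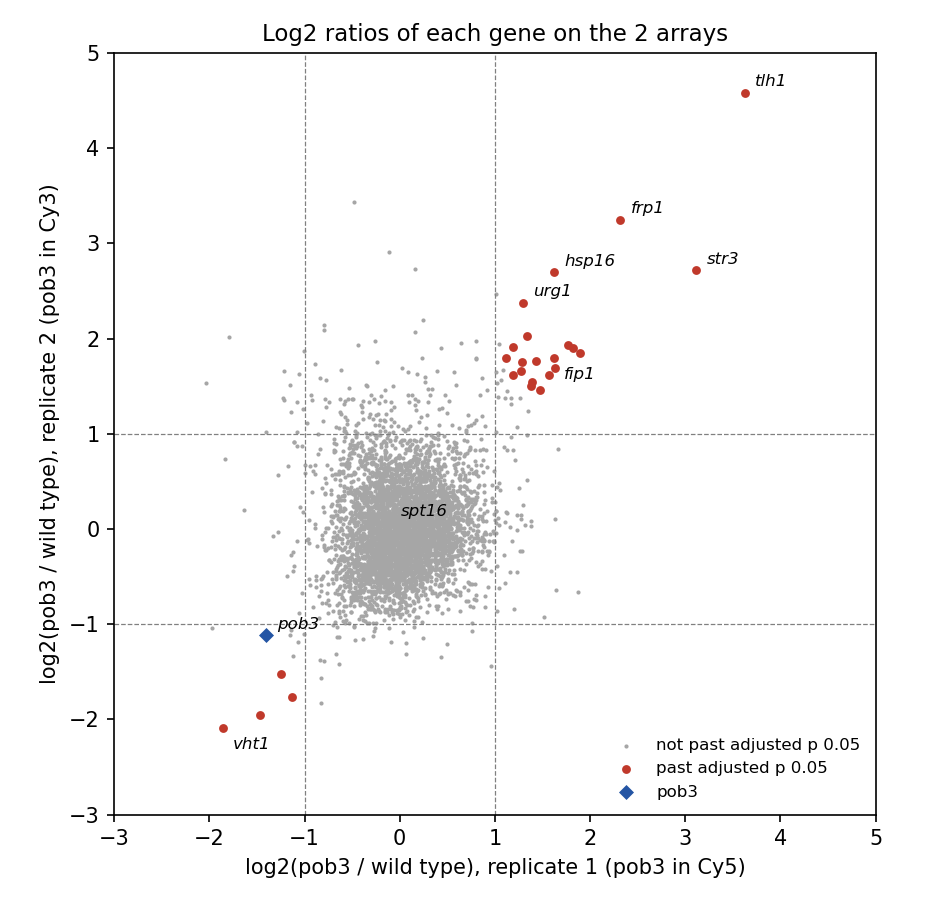
Log2 ratio of pob3 over wild type of 4766 genes on replicate 1 (horizontal axis) against replicate 2 (vertical axis), with 25 genes past an adjusted p of 0.05 in red, pob3 as a blue diamond and dashed lines at 2-fold. The red points lie beyond the dashed lines on both axes, 21 of them at the upper right and 4 at the lower left.

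The gene lists fixed in advance were compared with all other genes by camera with a preset correlation of 0.01, and 4 of 25 passed an adjusted p of 0.05. Iron and copper homeostasis genes rose as a list, with a mean log2 ratio of 0.48 over 22 measured members (0.51 and 0.46 on the arrays, adjusted p = 0.000491). The call ended with an estimated correlation (adjusted p = 0.980). Of these members 4 rose (str3, frp1, fip1 and fio1), 1 fell (vht1, the biotin transporter) and 17 did not pass the test. Adjusted over the list alone, 5 rose and 1 fell. The products of fip1 and fio1 act together in high-affinity iron uptake. The metallothionein gene zym1 had a log2 ratio of 0.98 ± 0.21 (adjusted p = 0.203), and the copper transporter gene ctr4 had -0.40. The median of the list was 0.34 and the SD across its members 1.06.

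Core environmental stress response genes also rose as a list, with a mean of 0.33 over 36 members (0.30 and 0.35 on the arrays, adjusted p = 0.000491), a call that ended with an estimated correlation (adjusted p = 0.980). Of the members 77.8% had a mean above 0. A single member, hsp16, rose, and 35 did not pass the test; adjusted over the list alone 4 rose. Values of the others with the smallest p were 1.32 ± 0.08 for hsp9 (adjusted p = 0.0518, saturated in the pob3 channel on 1 array), 1.15 ± 0.12 for the glutathione S-transferase gene gst2 (adjusted p = 0.0937) and 0.98 for zym1. The catalase gene ctt1 had 0.56 and fbp1, of gluconeogenesis, had -0.48. The list fixed for proteasome genes had a mean of 0.22 over 33 members (0.12 and 0.31 on the arrays, adjusted p = 0.0339). The call ended with an estimated correlation (adjusted p = 0.980), without the spot filter (0.0570) and with the first or second spots alone (0.0510 and 0.0609). The naming pattern also took in tbp1, of the TATA-binding protein, and pam17, of mitochondrial import, and without them the mean was 0.21 (adjusted p = 0.0459). The list had 0 members past the test over all genes and 1, rpn10 (1.33 ± 0.45, adjusted p = 0.0612), adjusted over the list alone. Cytosolic ribosomal protein genes fell as a list, with a mean of -0.13 over 117 members (adjusted p = 0.00202). With median centring the mean was -0.55 (adjusted p = 7.2e-20), and with an estimated correlation the call ended (adjusted p = 0.980). The list also took in rpp1, rpp21 and rpp40, of ribonuclease P, without which the adjusted p was 0.00173. Of the members 0 passed the test, over all genes or adjusted over the list alone. Their means were -0.22 on replicate 1 and -0.03 on replicate 2. Members with the smallest p were rps1002 and rps001 (-0.77 ± 0.21). None of the 25 lists passed with an estimated correlation or by fry, which tests whether a list moves one way. Both rest on 1 residual degree of freedom here, so missing the threshold with either says little. The correlations that camera estimated for the iron and copper (-0.04), stress response (-0.03) and proteasome (-0.008) lists lay below the preset 0.01. A higher correlation therefore did not end those 3 calls, but an estimate on 1 degree of freedom cannot show that members are uncorrelated. For ribosomal protein genes the estimate was 0.214, so correlation may contribute there.

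The remaining 21 fixed lists did not pass. Among amino acid and nitrogen regulated genes, the uracil-regulated genes urg1 and urg2 rose and 36 of 38 members did not pass the test, with 6 higher and 1 lower adjusted over the list alone; leu2 had 1.38 ± 0.41 and isp7 1.01. In the respiratory chain and ATP synthase list 1 of 51 members, cox1, rose, and sdh7 was the lowest of those with the smallest p. Of 22 heat shock and chaperone genes hsp16 rose, and hsp20 had -0.41. Of 40 centromere, kinetochore and cohesin genes fta6, of the kinetochore, rose, and of 30 mitosis and septation genes the kinesin gene klp8 rose. In these 5 lists adjusted p-values of camera lay between 0.378 and 0.974.

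Of the lists closest to the subject of the series, heterochromatin assembly factors (31 members, mean -0.01, adjusted p = 0.819), RNA interference factors (15, mean 0.03, adjusted p = 0.974), core histones and variants (10, mean 0.08, adjusted p = 0.819) and FACT and other histone chaperones (20, mean -0.12, adjusted p = 0.378) did not pass, and 0 of their members passed the test over all genes. The FACT list includes pob3 itself, which lowers its mean, and its median was -0.006. Adjusted over that list alone, 1 member, pob3, was lower. Single values were 0.57 ± 0.13 for the histone H3 lysine methyltransferase gene clr4, 0.05 ± 0.27 for the HP1 homologue gene swi6, 0.08 ± 0.08 for epe1, 0.31 ± 0.08 for ago1, -0.36 ± 0.37 for dcr1 and 0.01 ± 0.15 for rdp1, with adjusted p-values between 0.664 and 0.993. Wild-type clr4 lay above background on 1 array only. Tf2 retrotransposons, whose near-identical copies share probe sequence, had a mean of 0.08 over 11 members, with 0.32 and -0.16 on the arrays (adjusted p = 0.819). A p that misses the threshold does not show equal levels.

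Genes near chromosome ends rose as a list: the 25 genes nearest each end of chromosomes I and II had a mean of 0.21 and a median of 0.12 over 62 measured members, which lie at 3 of these ends (0.26 and 0.16 on the arrays, adjusted p = 0.0300 over 3 positional lists). The call ended with an estimated correlation (adjusted p = 0.388), fry (0.341), an offset of 10 (0.0501), both channels required above background (0.146) and the first spots alone (0.0691). Of these genes, tlh1, SPAC750.07c and SPAC212.08c rose and 59 did not pass the test; adjusted over the list alone 5 rose. SPAC212.06c, near tlh1, had 1.28 ± 0.36 (adjusted p = 0.0632). With 10 genes per end the mean was 0.46 and the median 0.16 (adjusted p = 0.00729, but 0.511 with an estimated correlation), and with 50 it was 0.11 and did not pass (adjusted p = 0.435). Of the 155 measured members of that widest list 5 rose, among them the iron uptake genes str3 and frp1. The 9 measured genes within 5 genes of pob3 all had means above 0, with 6 above 0 on both arrays, together 0.32 (0.19 and 0.45 on the arrays, adjusted p = 0.0268). This call ended with an estimated correlation (adjusted p = 0.388), fry (0.341), median centring (0.111), print-tip loess (0.0863) and the first spots alone (0.0691). None of them passed singly, and the highest was SPBC609.01 at 0.52 ± 0.49. Camera with an estimated correlation and fry rest on 1 residual degree of freedom, so missing the threshold with them says little. The estimated correlation was 0 for the genes near pob3 and 0.01 for the subtelomeric list, about the preset or below. A higher correlation therefore did not end either call, but an estimate on 1 degree of freedom cannot show that members are uncorrelated. Adjacent genes on a chromosome had an r of 0.204, which the preset of 0.01 does not allow for. The genes near pob3 were not set against random runs of genes. Genes flanking the centromeres did not pass (51 members, mean -0.02, camera adjusted p = 0.315), and 0 of them passed the test. Tested by fry for change in either direction, that list had an adjusted p of 0.0128, but 0.192 with 5 or with 20 genes per side; it included gua2 at 0.67 ± 0.56 and cbp3 at -0.58 ± 0.30.

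**Figure D2:**
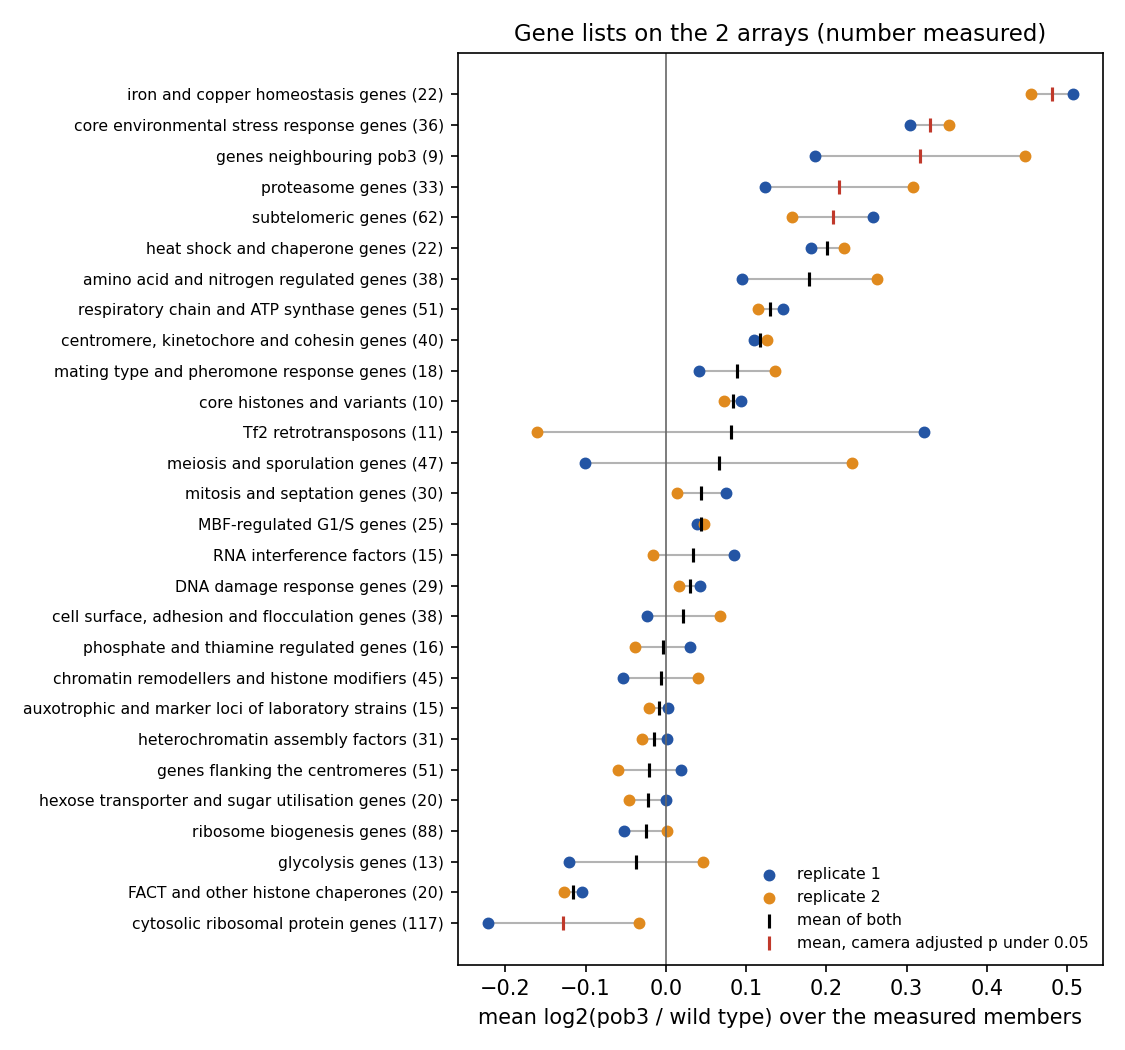
Mean log2 ratio of pob3 over wild type of the measured members of each list on replicate 1 (blue) and replicate 2 (orange), with the mean of both as a tick, red where the camera adjusted p was under 0.05. Iron and copper homeostasis genes lie highest (0.48) and cytosolic ribosomal protein genes lowest (-0.13).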

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

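Several probes outside the comparison lay above background more often than the empty and buffer spots, of which 1.95% did so in Cy3 and 6.26% in Cy5. Luciferase control probes did so in 95.3% of spots in Cy3, with log2 ratios of pob3 over wild type of -0.85 on replicate 1 and -0.79 on replicate 2 (SD between spots 0.35 and 0.47). The E. coli control probes did so in 74.2%, with 0.14 and -0.41 on the arrays. Elongation factor control probes did so in 100% (-0.19 and -0.38), reporter and marker probes in 89.3% (-0.10 and -0.33), intergenic probes in 47.5% (0.63 and -0.07) and intronic probes in 87.5% (0.17 and -0.41). The labels do not say what RNA, if any, was added for the control probes, and no explanation was tested.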

How the results depend on the processing

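The alternatives with print position medians and with the submitters' values for replicate 2 were chosen after the data were seen. The count of 25 genes past the threshold was 45 without background correction, 11 with an offset of 10, 0 with median centring, 56 with print-tip loess, 53 with arrays scaled to equal spread, 39 with both channels above background, 49 and 53 with the first and second spots alone, 38 with an intensity trend and 52 at a threshold of 0.10. It was 62 with print position medians subtracted, 63 with print-tip loess in addition and 68 with the submitters' values for replicate 2. A dye term on the 4 spot files gave 1730, where the spread is that between spots of an array. It stayed within 1.5 times at 21 without a filter and 30 with duplicateCorrelation. The count of 47 genes over 2-fold on both arrays was 154 at 1.5-fold, 74 in the mean alone, 30 in all spot files, and 126 to 225 with a single array. The pob3 ratio of -1.26 (adjusted p = 0.0612) passed the threshold at -1.19 without background correction, -1.48 with print-tip loess, -1.27 with equal spread, -1.26 with both channels, -1.19 and -1.32 with the first and second spots, -1.20 with print position medians, -1.44 with print-tip loess and print position medians and -1.37 with the submitters' values. Its adjusted p ranged from 0.00147 to 0.458. The spt16 ratio changed sign to 0.0216 with median centring, 0.20 with the second spots, 0.0057 with print position medians and 0.07 without replicate 1. The r of 0.155 between arrays turned to -0.0729 with median centring and was 0.129 with print-tip loess, 0.255 with print position medians and 0.241 with both. Of 4 fixed lists past the threshold 0 remained with an estimated correlation or fry, and other settings gave 3 to 5, with 4 once misassigned members were left out, a setting also added after the data were seen. Of 2 positional lists 1 passed with an offset of 10, median centring, print-tip loess, both channels or 50 genes per end, and 0 with the first spots, an estimated correlation or fry. Camera with an estimated correlation and fry rest on 1 residual degree of freedom, so lists lost with them say little. Of the 25 genes past the threshold 14 missed it with an offset of 10, 25 with median centring, 5 without a filter, 5 with duplicateCorrelation and 1 with the first spots. None turned its direction, though the submitters' values cover 17 of them only. Their ratios moved by at most 0.07 with an offset of 10 and 0.16 with median centring, where tlh1 had 4.10 (adjusted p = 0.0503). The cause was not tested except where print position is weighed elsewhere. The submitters' values could not be run for both arrays, as the column for replicate 1 held 0 gene spots, nor for the gene lists. Leaving out an array left no residual degree of freedom, hence no test. At least 96.6% of gene spots per file and channel lay above background, so low signal limits few ratios.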

Other observations

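Probes for 3 mitochondrially encoded genes were measured, and all had ratios above 0 on both arrays. They are cox1 (1.59 ± 0.03, adjusted p = 0.0238 in limma), cob (0.96 ± 0.33, adjusted p = 0.245) and cox2 (0.75 ± 0.06, adjusted p = 0.458), of which cox1 passed the threshold. The group has fewer than 5 members and was not tested as a list. The 23 wtf genes, a family of meiotic drivers with similar copies, had a mean of -0.04 (-0.16 and 0.08 on the arrays) and 0 past the threshold, and the 13 probes named SPAC1348 had a mean of 0.04 (0.19 and -0.11) and 0 past it. These groups were chosen after the data were seen.

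Among neighbouring genes on a chromosome, 4 pairs had both members over 2-fold higher on both arrays, against a mean of 0.233 and a highest of 3 in 1000 shuffled gene orders. They are tlh1 with SPAC212.08c, fip1 with fio1, leu2 with SPAC9E9.04 and apc14 with etf1. The members of the tlh1 pair were printed in the same block, as in only 3 of 4003 neighbour pairs, and those of the other 3 pairs share a print position in different blocks. The shuffled orders do not keep these print layouts, so the comparison does not allow for them. This count was chosen after the data were seen.

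In the 3 patterns that follow, the tests of dye bias, of print position, of the subtelomeric median and of runs of consecutive genes were chosen after the results were seen. The criterion of the test across arrays was also tightened after its result by adding a bootstrap bound, so that the noise of 1 array is judged by the value after print position medians were subtracted. Also after their results, 2 tests were taken as undecided, those of dye bias and of the subtelomeric list without its strongest members. No biological explanation beyond the pob3 contrast itself was tested.

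The log2 ratios of the arrays correlated at 0.155, while duplicate spots correlated at 0.797 on average. A local effect of the slide surface as the whole cause is argued against by neighbouring spots of different genes (r 0.322, under 0.5 times 0.797, the limit set beforehand), though blocks held 10.4% to 20.3% of the variance, so a part stays open. Noise of dim probes is argued against by the 1589 brightest genes (r 0.106). A gene-specific dye bias larger than the shared effect stays open, as the covariance was 0.0333 (0.0210 to 0.0456) with loess and -0.0222 (-0.0363 to -0.0064) with median centring. A dye bias shared by print positions is a candidate explanation for part of the pattern, as position medians of the arrays had an r of -0.617 and subtracting them moved the r of the arrays to 0.255, and the rest stays open.

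Subtelomeric genes had a mean of 0.21, above 99.96% of 10000 random lists matched on intensity, which ignore that neighbouring genes correlate. With the mean of each intensity bin subtracted it was 0.16, above 99.2% of random runs of consecutive genes, which together argues against dim probes as the whole cause. Without the 4 members over 2-fold on both arrays the mean was 0.07, above 70.0% of matched lists, but these members were removed by their outcome, so this decides nothing. The median of the whole list, 0.12, lay above 95.8% of the medians of matched lists, short of the bound used for the mean. Whether the shift rests on a few members, tlh1 among them, or on the region as a whole stays open.

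Neighbouring genes on a chromosome had correlated ratios (r 0.204 over 4003 pairs, against -0.03 to 0.03 in 95% of shuffled orders). This correlation held without genes over 2-fold on both arrays (r 0.197), which argues against a few strong pairs. Printing near each other is argued against by pairs in different blocks (r 0.196), which were 4000 of the 4003, with 3991 in blocks that do not touch. The 2899 pairs that share a print position had an r of 0.244 and the others 0.129, so a shared print position may contribute, and with position medians subtracted the r was 0.181. Across arrays the r was 0.0282 (upper bound of shuffled orders 0.0221), far below the values within each array, so most of the unadjusted correlation was not shared by the arrays. With position medians subtracted the r across arrays was 0.105 (lower bound 0.0785). This argues against the noise of 1 array and against a shared print position as the whole cause, in both cases only after that subtraction. The rest stays open.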
